A study of Caenorhabditis elegans with 2 samples.

How the data were processed

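The series holds chromatin immunoprecipitation followed by sequencing (ChIP-seq) of LIN-38 in whole Caenorhabditis elegans animals. Per the labels, the animals carried a CRISPR insertion that fuses EGFP and epitope tags to the endogenous lin-38 gene, chromatin was sheared by sonication and LIN-38-EGFP was recovered with an antibody against GFP. Animals were collected as L4 larvae, the last larval stage, 48 hours after synchronisation. There were 2 samples, biological replicates 1 and 2 of 1 group. Control libraries and read alignments were not analysed here. The files hold no read counts, so the depth of each sample is unknown and no value below carries an interval that would need it.

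The authors deposited 8 peak lists on the ce11 assembly. Per the labels and the list of outputs deposited with the samples, each sample has a ranked list and a thresholded list made from its own alignments, and the whole series has 2 ranked lists, a thresholded list and a conservative thresholded list made from the alignments of both samples. The irreproducible discovery rate (IDR) ranks peaks by how well they repeat between a pair of inputs. The aligner, the peak caller and their versions are not given in the sources used here. Each deposited peak carries a signal value, which is the authors' own score for the height of the peak; its scaling is not stated, so it was used to rank, describe or filter peaks, to set both replicates side by side and to compare promoter peaks with other peaks of the same list, and a difference in it is not a difference in occupancy. The deposited score column, a scaled IDR, was at least 830 in every thresholded list. In the deposited ranked lists, the −log10 of the global IDR of peaks with that score was 2.00 or more after rounding, which is an IDR of 0.01. The deposited −log10 q values were read but not used for any result. Small numbers of ranked peaks with a passing score were missing from the thresholded lists (29 for the conservative list, 26 for the other series list, 19 and 24 for replicates 1 and 2), and the reason is not given.

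The conservative list was the main peak set. It held 5431 peaks, of which 26 lay on mitochondrial DNA and were left out, so that 5405 nuclear summits remained, in 5108 separate regions. All 5431 peaks were found in 1 of the 2 ranked lists of the series. At 91.9% and 91.5% of that list's peaks, its 2 per-input signal values also occurred, exactly, among the ranked values of replicates 1 and 2. That comparison only identified the list, and the 2 input columns were not used as values of a sample. Every value per replicate is from the replicate's own ranked list, from the peak that overlaps and has the nearest summit.

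Coordinates are ce11, counted from 1. No peak lay beyond the end of a chromosome of the reference genome, WBcel235, which is the same assembly. Genes came from Ensembl release 115. It holds 19973 protein-coding genes on the 6 nuclear chromosomes, with 29314 distinct annotated 5′ ends. A gene was counted as having a promoter peak when a summit lay from 500 bp upstream to 200 bp downstream of any of its 5′ ends; such windows cover 16.4% of the nuclear genome.

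Shares of summits in promoter windows, other features and noncoding gene classes were compared with 10000 circular shifts of the summits along each chromosome, two-sided, which keep the spacing of the peaks. Each summit was given to 1 feature only, with promoter windows taken before small RNA genes, coding exons, UTRs and introns. Genes on X against autosomes, genes in the centre against the arms of autosomes, and 32 gene lists against all other protein-coding genes were compared with Fisher's exact test, two-sided. The centre is the middle part of a chromosome cut into 3 equal lengths. Signal values of promoter and other peaks were compared by a permutation test of the difference of median log2 values with 100000 resamples. The 2080 distinct 6-mers, counted together with their reverse complements, and 14 fixed sequence patterns were counted in 100 bp windows at the summits and in 2 windows of the same width centred 300 bp to each side. Fisher's exact test compared them, and a 6-mer also had to be at least 1.5 times as frequent at the summits. Families of tests were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. In the comparison of settings, the odds ratio of a list with a peak at every gene was taken with 0.5 added to each count. Intervals of shares are Wilson 95% intervals and those of odds ratios are exact 95% intervals. Peaks and genes are not replicates, and tests across them describe these 2 samples together. Between samples there is no test, because 1 group of 2 replicates allows none.

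Gene lists, sequence patterns, tests and most alternatives were fixed before the data were examined. The genes named were also fixed by a rule. It takes the nearest protein-coding gene for each of the 20 peaks with the highest signal value that overlapped a peak of both replicates and lay within 1000 bp of a 5′ end; the members with a peak of the synMuv, DREAM, heterochronic and vulval lists; up to 4 members with the highest signal values of each other list past the threshold; and lin-38 itself. Many lists were made from name patterns and took some genes of other kinds. The chemoreceptor pattern, for example, took the serpin gene srp-7. Among protein-coding genes 205 share a symbol with another gene, 36 of them histone genes. One summit can lie in the promoter windows of more than 1 gene, which was so for 564 summits (22.3% of promoter summits), and each such gene was counted.

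Alternatives were the other thresholded list of the series, the top 50% of peaks by signal value, each replicate's own thresholded list alone, wider and narrower promoter windows, assignment of each peak to the nearest 5′ end alone, a background of genes with any candidate peak of the ranked lists, other overlap rules, and 200 bp windows. For sequences, a further comparison set was candidate promoter peaks that failed the threshold, matched for GC content in 10 bins. Alternatives chosen after seeing the data were promoter summits alone against that matched set, and summits without those whose central 31 bases recur in the genome.

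Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used. The tests were tried on simulated data. With summits placed uniformly, 1 of 40 runs of the promoter test fell under the threshold, and with summits planted in promoters 40 of 40 did. Of simulated lists at 4 times the odds, 60 of 60 were called, and of lists at the base rate 0 of 580. Each gene was drawn independently there, so these counts say nothing about calls where 1 summit counts for more than 1 gene. A planted 6-mer ranked first in 5 of 5 runs, and 0 6-mers were called with none planted. Both sets of windows in those runs came from random genome positions. The runs therefore say nothing about calls that a difference in GC content between summits and flanks would bring. For the signal test, 0 of 20 runs without a shift and 20 of 20 runs with a shift of 0.3 on the log2 scale fell under the threshold.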

Results

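LIN-38 is a nuclear protein of the synMuv A class, whose genes act redundantly with the synMuv B class to keep vulval fates from being induced in the worm. Its binding was mapped by ChIP-seq in 2 biological replicates of whole L4 larvae that expressed LIN-38-EGFP from its own locus. The conservative list made from both samples held 5431 peaks with a median width of 376 bp, of which 5405 were nuclear. Replicate 1's own list held 4429 nuclear peaks and replicate 2's held 4474. The peak lists give positions and a signal value per peak, and no read counts, so the depth of the samples is unknown. The comparisons that 1 group of 2 replicates allows are between the replicates, and between the peaks and the rest of the genome.

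The first comparison asked how far the replicates gave the same sites. The strongest sites, such as the promoters of cdc-48.1, which encodes a AAA ATPase that extracts ubiquitinated proteins, and of the ribosomal protein gene rpl-7A, were in both lists with closely similar values. At cdc-48.1 the signal value was 8076 in replicate 1 and 7890 in replicate 2, and at rpl-7A it was 7154 and 6827. Of replicate 1's peaks, 79.7% (95% interval 78.5 to 80.9) overlapped a peak of replicate 2 by at least 1 bp, and 78.5% (77.3 to 79.7) of replicate 2's peaks overlapped one of replicate 1. Circular shifts of one list gave means of 2.95% and 2.90%. Sharing between these thresholded lists depended on strength. In the quartile with the highest signal values 99.0% of replicate 1's peaks and 98.7% of replicate 2's were shared, and in the lowest quartile 46.3% and 41.6%. Overlap with the other replicate's ranked list, which is far longer, was 99.0% and 98.8% in the highest quartile and 96.2% and 95.3% in the lowest. How much overlap chance gives with the ranked lists was not measured.

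**Figure D1:**
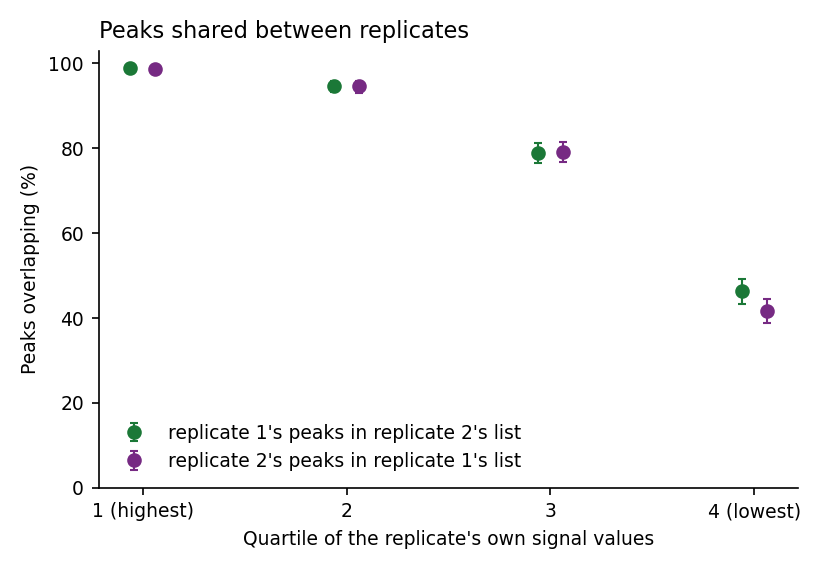
Share of each replicate's thresholded peaks (vertical axis, percent) that overlap a thresholded peak of the other replicate by at least 1 bp, by quartile of its own signal value (horizontal axis). Points are shares and bars are Wilson 95% intervals; sharing falls from 99.0% and 98.7% in the highest quartile to 46.3% and 41.6% in the lowest.

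Across the 5342 conservative peaks with a value in both samples, log2 signal values had a Pearson r of 0.957 and a Spearman rho of 0.915. These are correlations across peaks, which are not independent replicates, and the conservative list was itself selected for repeating between inputs. The median log2 ratio of replicate 1 over replicate 2 was 0.04, with an SD of 0.40 across peaks. Of the 5405 peaks, 3491 (64.6%) overlapped a peak in both replicates' own lists and 946 (17.5%) in neither.

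The second comparison asked where in the genome the peaks lay. Summits were concentrated in the promoter windows of protein-coding genes. A promoter window held 2531 of the 5405 summits, 46.8% (45.5 to 48.2), against 16.4% when summits were shifted. This is a 2.85-fold excess, with p = 0.0001 by circular permutation, the smallest the shifts can give. These summits marked 2910 protein-coding genes, 14.6% of the total. The median position of these summits was 146 bp upstream of the nearest 5′ end, and 82.8% lay on the upstream side. As the window reaches 500 bp upstream and 200 bp downstream, this median and part of this share follow from the window. Of the summits outside promoter windows and not near small RNA genes, those in coding exons made up 5.18% of all summits against 21.2% after shifting, and those in introns 15.5% against 30.8%. Peaks at promoters were also taller than all other peaks pooled: the median signal value was 283 at promoter peaks and 170 at other peaks, a log2 difference of 0.73 (permutation test, p = 1e-05, the smallest the resamples can give). Among those other peaks, the 405 near tRNA, snRNA, snoRNA, rRNA or microRNA genes had a higher median than promoter peaks, 342.

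Ribosomal protein genes recurred among the 20 strongest peaks that met the naming rule, beside genes of varied function. The highest was at cdc-48.1, with a signal value of 15912 on chromosome II from 10563319 to 10563811. Its summit at 10563576 was between genes, 169 bp upstream of the 5′ end. On chromosome IV followed a peak shared by Y17G9B.5 and the ribosomal protein gene rpl-20 (14968), one shared by rpl-7A and the SET-domain gene set-21 (13948), and one shared by rpl-12 and lin-54 (12924), the latter encoding a DNA-binding subunit of the DREAM complex. Next came eelo-2 (11752), ntl-11 (11565), and ska-3 with rps-12 (11234). Further strong peaks lay at dnj-28, a J-domain co-chaperone gene (8972), ints-4 of the Integrator complex (8946), ekl-4 with rps-20 (8890), mtcu-2 (8415), atp-1, a subunit of mitochondrial ATP synthase (8378), the cohesin loader gene scc-2 (7590), rps-15 (7480) and mrps-7 (7378). The remaining peaks lay nearest to Y39B6A.43 (10239), K08F11.1 (10327), Y62F5A.12 (9087), F48A11.4 (7794) and W08E12.7 (7602); those nearest to K08F11.1 and Y62F5A.12 were within 1000 bp of a 5′ end but outside its promoter window. In all 20 the replicates' log2 ratio lay between -0.06 and 0.19.

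The gene that encodes the tagged protein carried a peak itself. At lin-38 the peak ran from 13575576 to 13575868 on chromosome II, between mrpl-37 and lin-38. Its summit at 13575720 was 205 bp upstream of lin-38, and its signal value was 771 (425 in replicate 1 and 342 in replicate 2). It ranked 758 among the 5405 peaks.

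**Figure D2:**
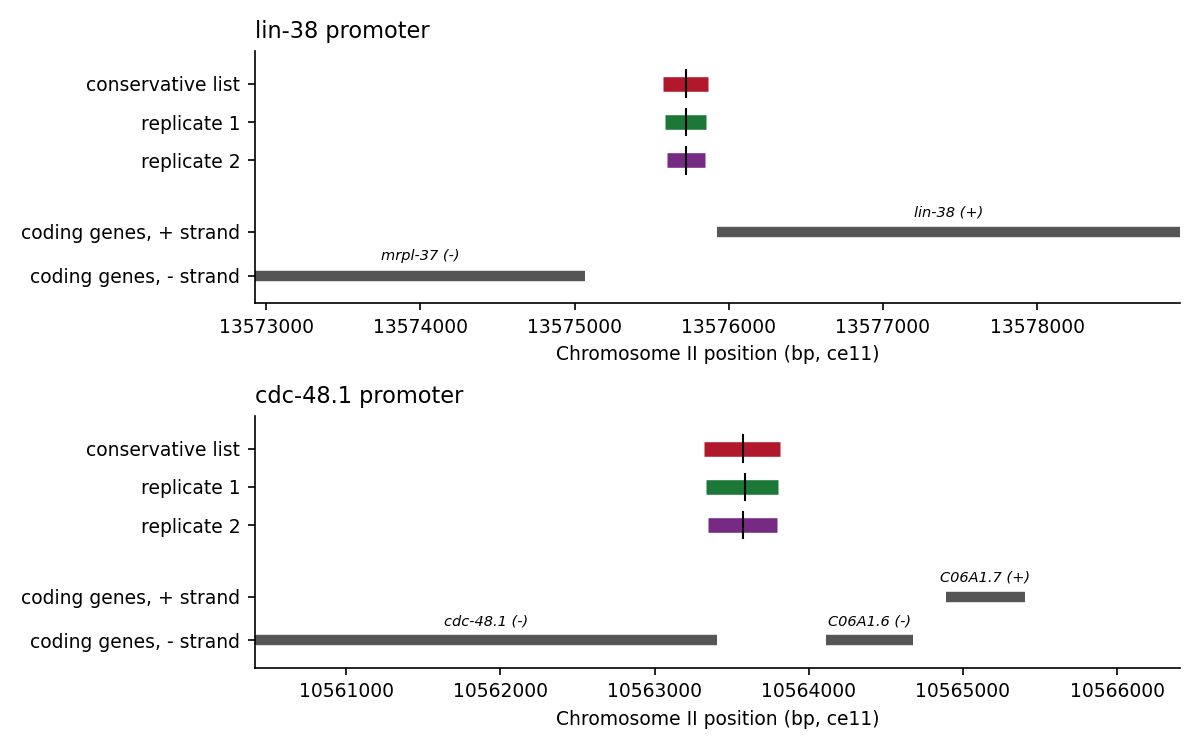
Maps of 6 kb at the lin-38 (top) and cdc-48.1 (bottom) promoters on chromosome II (horizontal axis, ce11 position in bp), with peaks of the conservative list and of each replicate's list as boxes, summits as black ticks, and coding genes as grey bars by strand. Both peaks are upstream of the 5′ end, with summits at 13575720 and 10563576 in the conservative list, and both are present in each replicate.

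The third comparison asked which gene groups had promoter peaks. Ribosomal protein genes, proteasome and translation genes, and genes of DNA replication had them far more often than other genes, and chemoreceptor, C-type lectin and F-box genes almost never did. Of the 32 lists, 13 passed the threshold in the direction of more peaks, 9 in the direction of fewer, and 10 did not pass.

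Ribosomal protein genes were the most complete of the large groups, with a promoter peak at 67 of 78 (85.9%, against 14.3% of other genes; odds ratio 36.5, interval 19.1 to 76.7, Fisher's exact test, adjusted p = 1.1e-43). rpl-20, rpl-7A, rpl-12 and rps-12 had the highest values. This depended on the promoter window: within 200 bp upstream and 100 bp downstream only 12 of 78 had a peak (odds ratio 2.09, Fisher's exact test, adjusted p = 0.052), and the summits of 55 of the 67 lay more than 200 bp upstream. With each peak given only to the nearest 5′ end, 43 of 78 had one (odds ratio 9.35). Translation factors had peaks at 29 of 42 genes (odds ratio 13.2), led by iff-2, an eIF5A gene (7241), and eef-1G (5067). Aminoacyl-tRNA synthetase genes had them at 17 of 32 (odds ratio 6.68), led by mars-1 (2348) and vars-1 (1598). Proteasome subunit genes had them at 24 of 33 (odds ratio 15.8), led by rpn-3 (6315), rpt-2 (2911) and rpn-9 (2778). Heat shock protein and co-chaperone genes had them at 33 of 60 (odds ratio 7.24), led by dnj-28, cct-1 (6983), hsp-90 (6724) and hsp-110, whose peak is also that of rpn-3 (6315). Ubiquitin conjugation genes had them at 24 of 63 (odds ratio 3.63), led by ubl-1 (3494) and ubc-6 (1972); in the narrow window this excess was gone (odds ratio 0.99, Fisher's exact test, adjusted p = 1.0).

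Genes of the respiratory chain had peaks at 38 of 65 (odds ratio 8.35), led by atp-1, cox-6B (6288), ucr-2.1 (3523) and atp-3 (2930). Splicing factor genes had them at 31 of 52 (odds ratio 8.74), led by snr-1, a core snRNP protein (3693); sym-4, second in that list (2959), entered through its name pattern. DNA replication and cell cycle genes had them at 39 of 71 (odds ratio 7.23), led by mcm-2 (4807) and cdc-6 (3185), which encode parts of the replication licensing machinery, and by the kinetochore genes hcp-1 (2632) and knl-3 (1910). Chromatin modifier genes had them at 29 of 80 (odds ratio 3.36), led by set-21 and by mes-2, the worm E(z) homologue (5367). Vesicle transport genes had them at 41 of 106 (odds ratio 3.74), led by rab-18 (5107) and vps-51 (4791). Germline and P granule genes had them at 20 of 39 (odds ratio 6.21), led by pos-1 (3296) and mex-1 (867), which encode RNA-binding proteins of the early embryo, then spn-4 (402) and glh-2 (381). The summits of pos-1, spn-4 and glh-2 also lay in the promoter window of another gene, which for spn-4 was spe-39 of the spermatogenesis list. By Fisher's exact test, adjusted p over these 12 lists ranged from 1.1e-43 to 6.9e-06. Genes that share a summit with another gene are not independent counts, and Fisher's exact test takes them as such. Among genes with a peak, these were 20 of 33 heat shock, 17 of 31 splicing, 37 of 67 ribosomal protein, 13 of 24 proteasome and 20 of 38 respiratory chain genes. In the other lists the share was smaller, such as 12 of 29 translation factor and 8 of 24 ubiquitin conjugation genes. Against the smaller background of genes with any candidate promoter peak, the synthetase (odds ratio 2.07, adjusted p = 0.088) and chromatin modifier lists (1.85, adjusted p = 0.052) no longer passed Fisher's exact test. On that background the lists that still passed had lower odds ratios, among them ribosomal protein (16.7), proteasome (5.88), translation factor (4.74), germline (3.67), DNA replication (3.59), heat shock (3.24), respiratory chain (2.94) and vesicle transport genes (1.72). The narrow window lowered proteasome genes to 6.58, translation factors to 5.16 and germline genes to 2.96, and germline genes had 4.13 with replicate 1's list alone. In the narrow window respiratory chain genes had 3.45, splicing factors 4.67 and heat shock and co-chaperone genes 3.18, and nearest-gene assignment gave 3.22 for the last and 6.85 for translation factors.

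**Figure D3:**
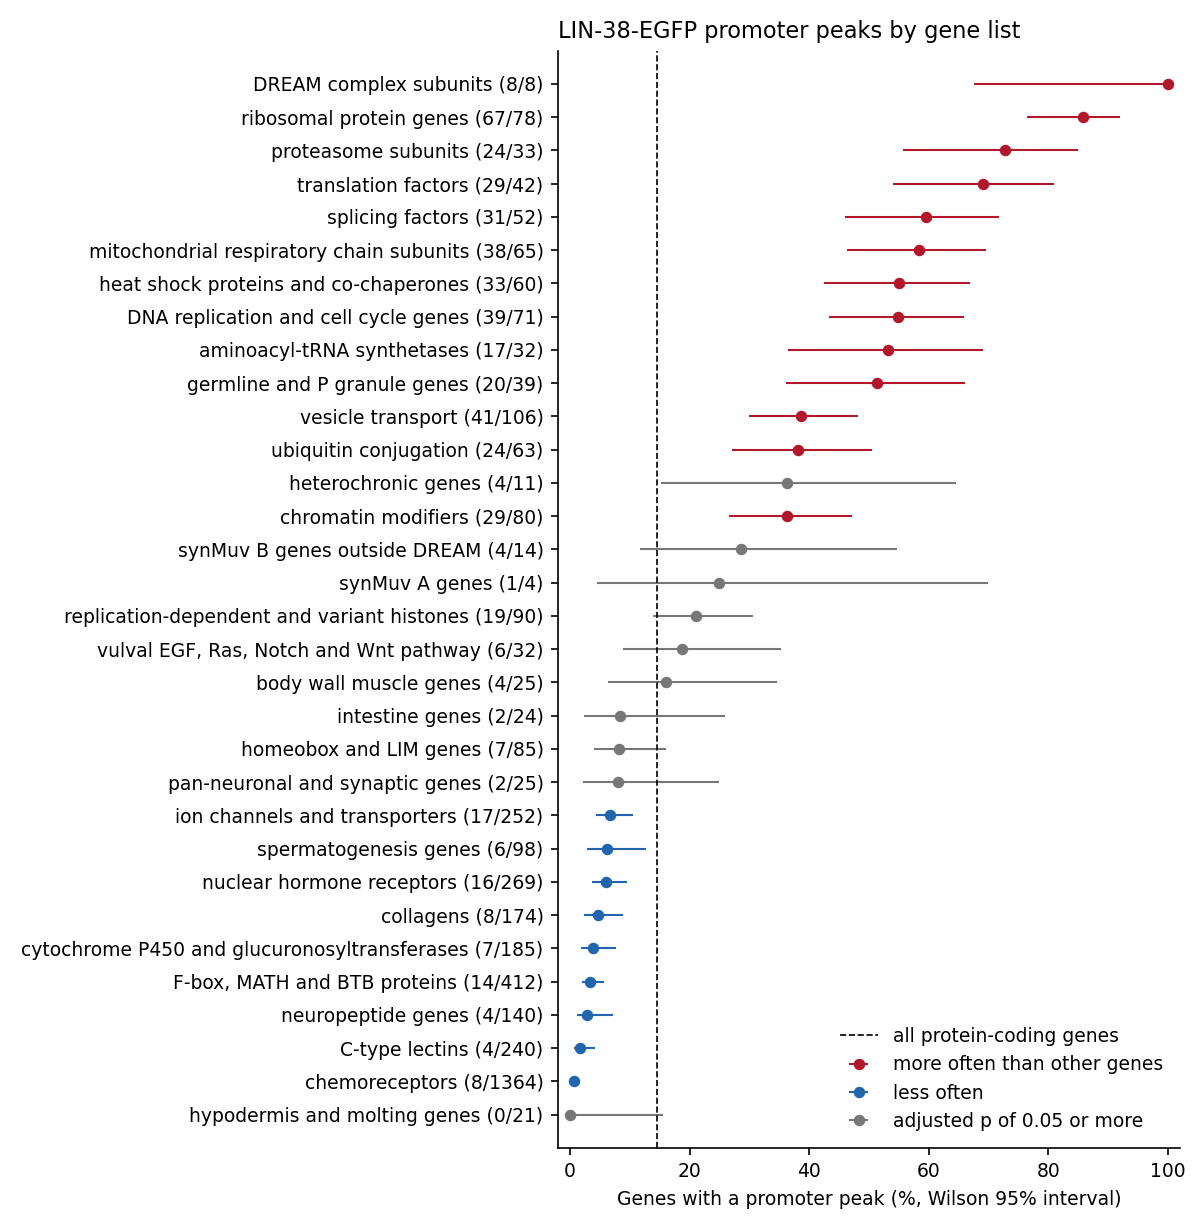
Share of genes with a promoter peak in each of the 32 gene lists (horizontal axis, percent); points are shares, bars Wilson 95% intervals, and counts stand after each name. Red lists had peaks more often than other genes, blue lists less often, and grey lists did not pass; the dashed line is the share of all protein-coding genes, 14.6%.

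The synMuv and DREAM genes were looked at one by one. All 8 genes for subunits of DREAM, the complex of the Rb homologue LIN-35 with E2F and MuvB proteins, had a promoter peak (against 14.5% of other genes; lower limit of the odds ratio 10.03, Fisher's exact test, adjusted p = 5.0e-07). Signal values were high at lin-54 (12924, the peak shared with rpl-12), efl-1 (6668), lin-35 (4791, shared with vps-51), lin-53 (2020, shared with nra-2) and lin-9 (1296). They were low at lin-37 (177), dpl-1 (123.9) and lin-52 (122). With either replicate's list alone 6 of the 8 had a peak, and in the narrow window 5 did. The peak at dpl-1 overlapped no peak of either replicate's own list. That at lin-37 overlapped only one of replicate 1's, and that at lin-52 only one of replicate 2's. The peak at efl-1, the E2F gene, ran from 16965625 to 16966107 on chromosome V, with its summit 189 bp upstream. Of the 14 synMuv B genes outside DREAM, 4 had a peak, lin-61 (823), lex-1 (587), lin-36 (375) and mep-1 (322), which was not distinguishable from other genes (odds ratio 2.35, interval 0.54 to 8.14, Fisher's exact test, adjusted p = 0.16). In the wider promoter window 8 of the 14 had one (odds ratio 6.06, Fisher's exact test, adjusted p = 0.0018). In the narrow window and against genes with a candidate peak there was no excess. Of the 4 synMuv A genes only lin-38 had a peak; lin-8 and lin-56 had candidate peaks in the ranked lists and lin-15A had none.

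Among the 32 genes of the vulval EGF, Ras, Notch and Wnt pathways, 6 had a promoter peak (odds ratio 1.35, interval 0.46 to 3.37, Fisher's exact test, adjusted p = 0.52). They were sur-2, a Mediator subunit gene (1145), lin-3, lin-7 (624), the Raf gene lin-45 (156), pop-1 (144) and lip-1 (119.3). The peaks at lin-45 and pop-1 overlapped no peak of either replicate's own list, and that at lip-1 only one of replicate 1's. lin-3 encodes the EGF signal of vulval induction and is the gene that synMuv proteins are known to keep silent. Its peak ran from 11053976 to 11054251 on chromosome IV, with a signal value of 709 (378 in replicate 1 and 323 in replicate 2) and a summit 205 bp upstream of a lin-3 5′ end, and it also lay in the promoter window of F36H1.12. Of the 11 protein-coding heterochronic genes, which time larval development, 4 had a peak (odds ratio 3.35, interval 0.72 to 13.2, Fisher's exact test, adjusted p = 0.085). lin-28 had a strong one (1584), and lin-66 (139), alg-1 (118) and lin-14 (110) had weak ones. The list passed in the wider window and with nearest-gene assignment (Fisher's exact test, adjusted p = 0.041 and 0.047). The peak at alg-1 overlapped no peak of either replicate's own list, and that at lin-14 only one of replicate 1's. Of the heterochronic microRNA genes, mir-48 had a summit within 200 bp, and lin-4, let-7, mir-84 and mir-241 had none.

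Large families with tissue-restricted or environment-facing functions lay on the other side. Chemoreceptor genes had a promoter peak at 8 of 1364 (0.587%; odds ratio 0.032, interval 0.014 to 0.063, Fisher's exact test, adjusted p = 2.7e-81). Of the strongest of those 8, sri-5 (1170) shares its summit with rsr-1, and srp-7 (1017) is a serpin gene taken by the name pattern. F-box, MATH and BTB genes had peaks at 14 of 412 (odds ratio 0.20), with fbxb-85 (1606) and bath-36 (927) highest, C-type lectin genes at 4 of 240 (0.098), with clec-126 (760) highest, and neuropeptide genes at 4 of 140 (0.17), with flp-23 (273) highest. Nuclear hormone receptor genes had them at 16 of 269 (odds ratio 0.37), led by nhr-47 (1138), and genes for cytochrome P450, glucuronosyl- and glutathione transferases at 7 of 185 (0.23), led by cyp-25A4 (801). Collagen genes had them at 8 of 174 (odds ratio 0.28), led by col-71 (3889), ion channel and transporter genes at 17 of 252 (0.42), led by slc-25A42 (3335), and spermatogenesis genes at 6 of 98 (0.38), led by spe-6 (829). By Fisher's exact test, adjusted p over these 9 lists ranged from 2.7e-81 to 0.021. The summits at fbxb-85, bath-36, nhr-47, col-71, slc-25A42 and spe-6 also lay in the promoter window of another gene. Those at clec-126 and flp-23 lay near tRNA genes. Such peaks cannot be credited to the named gene alone. Against genes with any candidate promoter peak, the lectin (odds ratio 0.53), cytochrome P450 (0.49) and spermatogenesis lists (0.62) no longer passed Fisher's exact test (adjusted p from 0.18 to 0.48). Spermatogenesis genes also did not pass Fisher's exact test with the narrow window (odds ratio 0.61, adjusted p = 0.44) or nearest-gene assignment (0.49, adjusted p = 0.12). With the top 50% of peaks (0.39, adjusted p = 0.083) or replicate 2's list alone (0.43, adjusted p = 0.052) they did not pass Fisher's exact test either, at odds ratios near the 0.38 above. Tissue markers did not pass in either direction: 0 of 21 hypodermis and molting genes, 4 of 25 body wall muscle genes, 2 of 24 intestine genes, 2 of 25 neuronal genes and 7 of 85 homeobox genes had a peak, and neither did histone genes, at 19 of 90. In the wider window histone genes passed toward more peaks (odds ratio 2.17) and hypodermis (0) and homeobox genes (0.47) toward fewer. On the candidate background histone genes (odds ratio 2.53, adjusted p = 0.031) and hypodermis genes (0 of 8, adjusted p = 0.047) passed Fisher's exact test in the same directions. Of the 19 histone genes with a peak, 15 share the summit with another gene, so they are not independent counts. With the top 50% of peaks the odds ratio of histone genes was 1.02. Against the candidate background chemoreceptor genes had an odds ratio of 0.27 and F-box, MATH and BTB genes 0.51; with replicate 2's list alone collagen genes had 0.15 and nuclear hormone receptor genes 0.15.

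The fourth comparison asked how peaks were spread over the chromosomes. Genes on X had promoter peaks much less often than autosomal genes. A peak was present at 148 of 2731 X genes (5.42%) and at 2762 of 17242 autosomal genes (16.0%), an odds ratio of 0.30 (interval 0.25 to 0.36, Fisher's exact p = 1.5e-58). Among autosomes the share was highest on I (24.8%) and III (22.99%), then IV (15.7%), II (14.1%) and V (8.77%). The peaks on X had a median signal value of 253 against 209 on autosomes, a difference that was not tested. The deficit was already present among candidates: 467 X genes and 6690 autosomal genes had a candidate promoter peak, and within those the odds ratio was 0.66 (interval 0.54 to 0.81, Fisher's exact p = 4.1e-05).

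Centres and arms of autosomes did not differ by more than chance: 16.6% of 6568 genes in the centres and 15.7% of 10674 in the arms had a promoter peak (odds ratio 1.07, interval 0.99 to 1.17, Fisher's exact p = 0.0997). The wider window (odds ratio 1.09, p = 0.025) and the candidate background (1.14, p = 0.010) moved this past the threshold of Fisher's exact test. Taken 1 by 1, chromosome V passed the threshold, with 10.9% in its centre and 7.57% in its arms (odds ratio 1.49, Fisher's exact test, adjusted p = 0.00045 over 5 chromosomes). Chromosome II leaned the same way without passing (odds ratio 1.26, Fisher's exact test, adjusted p = 0.063), while III (0.84), I (0.91) and IV (0.94) leaned the other way without passing. The pooled value thus averages over both directions, and the difference between chromosomes was not tested.

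**Figure D4:**
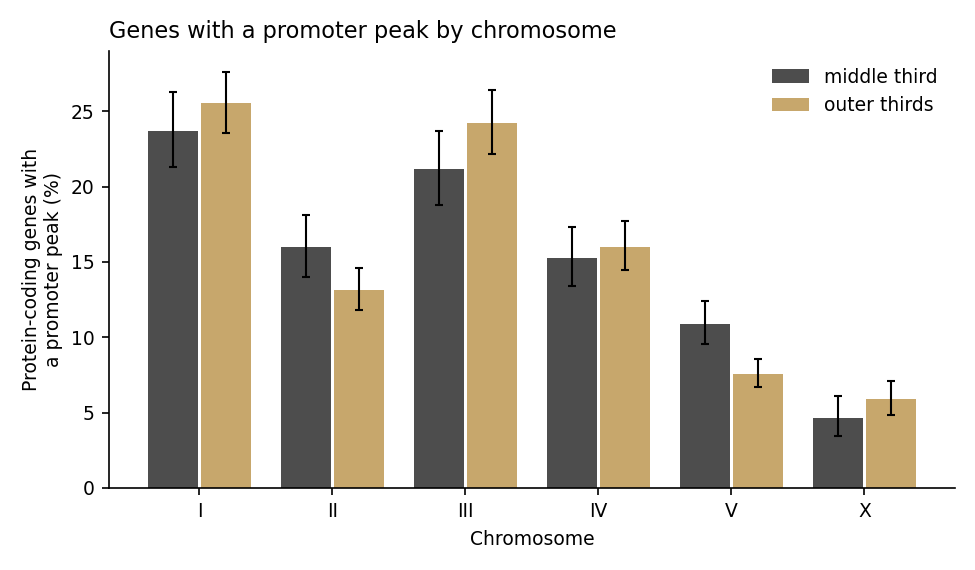
Share of protein-coding genes with a promoter peak (vertical axis, percent) in the centre and the arms of each chromosome (horizontal axis); bars are shares with Wilson 95% intervals. X lies below every autosome, with 4.61% in its centre and 5.87% in its arms.

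The fifth comparison asked whether peaks lay at noncoding genes. Genes for tRNAs and for small nuclear and nucleolar RNAs often had a peak nearby. Of 612 tRNA genes, 332 (54.2%, interval 50.3 to 58.2) had a summit within 200 bp, and 5.70% of summits lay there against 0.226% after shifting, a 25.2-fold excess. Without summits whose central sequence recurs in the genome, an alternative chosen after seeing the data, the excess was 11.3-fold. snRNA genes had one at 50 of 129 (16.4-fold), snoRNA genes at 101 of 346 (9.75-fold) and microRNA genes at 23 of 261 (3.77-fold). piRNA genes, at 58 of 15363 (0.255-fold), and pseudogenes, at 77 of 2128 (0.425-fold), lay near summits less often than chance. Adjusted p was 0.00013 for each of these 6 classes, from p = 0.0001 by circular permutation, the smallest the shifts can give. Long intergenic RNA genes (18 of 194, adjusted p = 0.39) and rRNA genes (0 of 20, adjusted p = 0.60) did not pass the circular permutation, although the former passed with replicate 1's list alone (1.70-fold, adjusted p = 0.029) and within 500 bp (adjusted p = 0.047). Copies of tRNA and snRNA genes are nearly identical, and how reads were divided among them is not given in the sources used here. Control libraries were not analysed here, so background at these genes was not measured.

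The sixth comparison asked which sequences marked the summits. Many CG-rich 6-mers were enriched, and the one that ranked first was GAGCGC with its reverse complement GCGCTC. It occurred in 17.8% of the 100 bp summit windows and in 2.40% of the flanking windows, a ratio of 7.43 (Fisher's exact test, adjusted p = 6.2e-250). It was concentrated within about 40 bp of the summit. Its share rose with signal value, from 7.33% of the weakest quartile of peaks to 36.5% of the strongest (odds ratio 7.25, interval 5.73 to 9.25, Fisher's exact p = 7.5e-80). It was present at the summits of lin-38, lin-28 and 4 of the 8 DREAM genes, efl-1, lin-35, lin-54 and lin-9. It was absent at those of the other 4, lin-53, lin-37, dpl-1 and lin-52, and at cdc-48.1, rpl-20, rpl-7A and lin-3. By position it marked 20.6% of promoter summits and, outside promoter windows, 8.15% of summits near small RNA genes and 25.3% and 3.21% of the remaining summits in introns and in coding exons.

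In all, 521 of the 2080 6-mers were enriched, and 292 of them contained CG. The next in rank were AGCGCG (13.6% against 1.78%) and ACGCGC (12.6% against 1.47%). The ratio to the flanks was higher for GCGCGC (9.02), ACGCGC (8.59) and AGCGCG (7.66) than for GAGCGC, which led by its share and adjusted p. Summit windows were richer in GC than the flanks, at 44.3% against 36.1%. Against candidate promoter peaks that failed the threshold, matched for GC, 143 6-mers were enriched, 132 of them among the 521. GAGCGC remained first, at 17.9% against 3.47%, a ratio of 5.14 (Fisher's exact test, adjusted p = 5.3e-106).

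**Figure D5:**
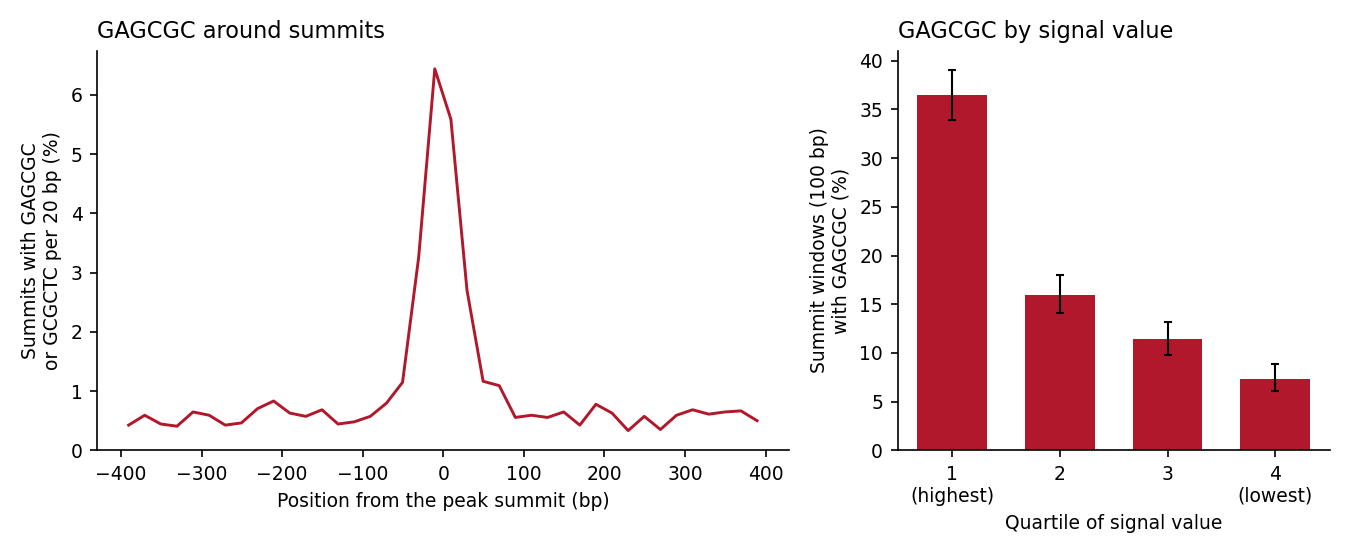
Left, share of the 5405 summits (vertical axis, percent) with GAGCGC or GCGCTC starting in each 20 bp bin around the summit (horizontal axis, bp). Right, share of 100 bp summit windows with it by quartile of signal value, with Wilson 95% intervals; it falls from 36.5% to 7.33%.

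Of the 14 sequence patterns fixed in advance, the E2F-like site TTYSSCGC was in 7.79% of summit windows and 2.72% of flanks (odds ratio 3.02, interval 2.59 to 3.53, Fisher's exact test, adjusted p = 1.4e-45), and it stayed more frequent than in the GC-matched set (odds ratio 1.77, adjusted p = 3.4e-08). By Fisher's exact test the same held for GAGA repeats (14.9% against 6.11%; 1.37 in the matched set, adjusted p = 3.9e-05) and CA repeats (9.42% against 4.91%; 1.37 in the matched set, adjusted p = 0.00078). The GC box (odds ratio 2.82), the E-box CACGTG (1.65) and the THAP-like core GGGCAN (1.61) were more frequent than in the flanks but not than in the matched set (odds ratios 0.81, 0.88 and 0.84; adjusted p from 0.069 to 0.40). The CHR-like element TTYRAA, bound by MuvB proteins, was less frequent than in the flanks (34.3% against 41.9%, odds ratio 0.73, adjusted p = 4.5e-20) and more frequent than in the matched set (39.4% against 31.5%, odds ratio 1.41, adjusted p = 5.1e-13), so its direction by Fisher's exact test depended on the comparison. GATA, homeodomain, heat shock, X-box and T-block patterns were less frequent than in the flanks (odds ratios from 0.39 to 0.72), and none of them passed against the matched set. Among promoter summits alone, a comparison chosen after seeing the data, GATA sites were less frequent than in matched candidates (odds ratio 0.76, Fisher's exact test, adjusted p = 0.0027). By Fisher's exact test the X-box pattern also did not pass with replicate 2's list alone (odds ratio 0.62, adjusted p = 0.094) or with the top 50% of peaks (0.38, adjusted p = 0.063). CRE-like and AP-1-like sites did not pass Fisher's exact test against the flanks or the matched set (adjusted p from 0.15 to 0.69). As the matched set can include peaks of the conservative list, not passing against it does not show equal frequency.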

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

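The test in this part was chosen only after the result was seen. Mitochondrial DNA lies outside the comparisons of the report, and peaks were present there in every thresholded list. The conservative list held 26 mitochondrial peaks, the other thresholded list of the series 26, replicate 1's list 26 and replicate 2's list 27, where a count of 0 would mean no signal.

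The highest mitochondrial peak of the conservative list had a signal value of 10205 and ranked 13 among all peaks. Together the peaks of that list covered 10183 of the 13794 bp of the mitochondrial genome, 73.8%, and in replicate 1 the cover was 60.4%. None of the 25 complete summit windows there held GAGCGC. How often it occurs in mitochondrial DNA as a whole was not measured, so its absence does not separate binding from background. A background raised by the many copies of mitochondrial DNA has no preferred position, and the wide cover is consistent with it. Input libraries were not used here, so binding of LIN-38 to some mitochondrial sites stays open, and no biological explanation was tested.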

How the results depend on the processing

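No paired analysis was possible because there is 1 group of samples. The depth of the samples is unknown, so what depth limits could not be measured. For the answers to the comparisons, 80 values under the alternatives kept their direction and side of the threshold or their size, 12 moved, 2 passed the threshold anew and 1 reversed. Among single genes, lists, classes and sequences 490 kept theirs, 21 fell short of the threshold, 12 passed it anew and 35 reversed. With 1 replicate's list at a time, the promoter share was 50.3 to 50.7%, genes with a promoter peak 2622 to 2632, the odds ratio of X 0.288 to 0.310, that of centres 1.04 to 1.07, lists with more peaks 13 to 13 and with fewer 8 to 9, noncoding classes nearer 4 to 5, the log2 signal difference 0.56 to 0.60 and enriched 6-mers 555 to 563. Of the 2622 genes from replicate 2 alone 2453 were among the 2910, and of the 2632 from replicate 1 alone 2474. In what follows the cause was not tested.

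Replicate overlap was 70.2% and 69.3% with a reciprocal overlap of 50%, and 75.5% and 74.8% with summits within 100 bp. The correlation was 0.661 over all ranked peaks and 0.928 without the top 5%. In the narrow promoter window 1606 genes had a peak, centres over arms had an odds ratio of 0.993 (Fisher's exact p = 0.913), and odds ratios turned for synMuv A (0), synMuv B (0.880), vulval (0.762), ubiquitin (0.986) and muscle genes (0). In the wide window centres over arms was 1.09 (Fisher's exact p = 0.025) and muscle 0.865. With the candidate background centres over arms was 1.14 (Fisher's exact p = 0.010), synMuv A 0.730, synMuv B 0.973, vulval 0.729 and muscle 0.729. With the top 50% of peaks vulval was 0.946, heterochronic 0.914, muscle 0.795 and AP-1-like sites 0.903. Without replicate 1 vulval was 0.684 and heterochronic 0.662, and without replicate 2 vulval was 0.941 and AP-1-like 0.775; the other value of heterochronic genes was 2.47 and that of AP-1-like sites 1.10.

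Enriched 6-mers numbered 312 with 200 bp windows, where CRE-like sites turned to 0.943. Against GC-matched candidates 143 6-mers were enriched and 0 patterns were less frequent, and odds ratios turned for CHR-like (1.41), E-box (0.884), GC box (0.813), CRE-like (0.649), AP-1-like (0.784), homeodomain (1.23), heat shock (1.01) and THAP-like (0.836) patterns. For promoter summits against matched candidates, chosen after seeing the data, 198 6-mers were enriched and 1 pattern, GATA sites, was less frequent, with CHR-like 1.59, E-box 0.948, GC box 0.831, CRE-like 1.0, AP-1-like 0.894, homeodomain 1.24, THAP-like 0.813 and T-block 1.05.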

Other observations

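Tests chosen only after the result was seen are those of GC content, of tRNA genes with unique flanks, of promoter summits against matched candidates, of summits without recurring sequence, of the position of summits by list, also among unshared summits, and of GAGCGC by list. The summits counted for ribosomal protein genes lay farther upstream of annotated 5′ ends than those of other genes. Whether these annotated ends are the sites where transcription starts was not examined. The positions are those of the summits counted for each list. For ribosomal protein genes the median position was 286 bp upstream of the 5′ end against 159 bp for other genes with a promoter peak (permutation test, p = 1e-05, the smallest the resamples can give, adjusted p = 0.00015 over 15 lists). Of their summits, 55 of 67 (82.1%) lay more than 200 bp upstream against 39.2%. A summit shared with another gene is counted for both, and 37 of the 67 had such a summit. Among genes whose nearest summit was unshared the medians were 286 bp for 31 ribosomal protein genes and 147.5 bp for 1778 others (permutation test, p = 0.00047). Nuclear hormone receptor genes also had distant summits (median 303 bp upstream, 16 genes, permutation test, adjusted p = 0.025), and the other 13 lists did not pass. GAGCGC was found at 17 of 41 promoter peaks of DNA replication and cell cycle genes (41.5%, against 20.3% of other promoter peaks; odds ratio 2.78, interval 1.39 to 5.45, Fisher's exact test, adjusted p = 0.040), and at 10 of 66 of ribosomal protein genes and 1 of 21 of germline genes, which did not pass.

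Some of the strongest peaks lay far from any annotated 5′ end of a protein-coding gene and so outside the rule for naming genes. They were chosen after their values were seen. The peak from 3456170 to 3456689 on chromosome III ranked 5 (signal value 12462); it lies within C34C12.2, 2077 bp from the nearest 5′ end of C34C12.1, and holds GAGCGC. On chromosome IV, a peak from 4727804 to 4728299 (10437, rank 10) lay 2891 bp from K08F11.1. Another from 4184744 to 4185167 (7786, rank 20, with GAGCGC) lay 1234 bp from K08D10.11. Neither summit was within a protein-coding gene. A peak on chromosome I from 2639530 to 2640087 (11130, rank 9), 1165 bp from F40E3.3, sits on sequence that recurs elsewhere in the genome. Recurring central sequence was found at 3.32% of promoter summits, 15.2% of other summits and 60.4% of summits near tRNA genes.

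Fewer X genes than autosomal genes had a promoter peak. A shortage of the leading sequence on X is argued against, since 14.3% of X promoters and 13.1% of autosomal promoters held it, and among genes that held it the odds ratio was still 0.399 (interval 0.304 to 0.520). Membership of the called lists is argued against too. The odds ratio was 0.263 (0.216 to 0.317) among genes of no list past the threshold, and 0.289 (0.154 to 0.522) among genes of lists with more peaks. The latter lists hold only 64 X genes and 664 autosomal genes, so leaving them out cannot test gene content beyond them. Lower recovery of all X DNA as the whole cause is argued against by tRNA genes only where all genes are the background. The odds ratio of tRNA genes was 0.641 (0.458 to 0.894), and 0.648 (0.455 to 0.922) with unique flanks, both above the interval of all protein-coding genes. Among genes with a candidate promoter peak, however, the odds ratio was 0.66 (0.54 to 0.81), and its interval overlaps both. Also, 60.4% of summits near tRNA genes sit on recurring sequence, so reads of autosomal copies may count at X copies. As the tRNA values are below 1 and background at tRNA genes was not measured, tRNA genes alone cannot decide, and a part played by recovery stays open. A hypothesis that stays open is that LIN-38 binding may depend on gene expression, which is low on X in the germ line; no biological explanation was tested, and ChIP-seq of animals without a germ line would test it.

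GAGCGC at summits was the other pattern weighed. The GC-matched set was fixed before the data were examined, but not its use to weigh this explanation. Total GC content of the windows is argued against, since the ratio of shares against GC-matched candidates was 5.14 (4.33 to 6.11), and 4.56 for promoter summits alone. Matching kept 4206 of the 5405 summits, at 41.6% GC against 44.3% for all. The matched candidates can include some peaks of the conservative list. The number of CG dinucleotides was not matched, so an effect of it was not tested. Repeated sequence is argued against, since without recurring summits the ratio to the flanks was 7.30 (6.34 to 8.39). As a hypothesis, LIN-38 or a partner may recognise this sequence or a related CG-rich one directly. No biological explanation was tested, and binding of purified LIN-38 to the sequence and to mutated forms would test it.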
